A study of Homo sapiens with 2 samples.

How the data were processed

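HepG2, a human hepatocellular carcinoma cell line, carried METTL14 with an HA tag from a lentiviral vector. METTL14 is the partner of METTL3 in the complex that writes N6-methyladenosine into RNA. The assay was PAR-CLIP, in which 4-thiouridine taken up into RNA is crosslinked to bound protein by long-wave UV light and then read as C in place of T, so that a T-to-C change marks a crosslinked uridine. Per the labels' protocols, cells were given 200 µM 4-thiouridine for 16 h and irradiated 3 times at 365 nm with 0.15 J/cm2. RNA bound to HA beads was trimmed with RNase T1, which cuts after G, and made into small RNA libraries. RNase T1 trimming and 4-thiouridine both select the sequences that can be recovered, so sites can be missed where uridines or suitable G positions are lacking.

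The series has 1 group of 2 libraries, replicates 1 and 2 of HA-METTL14. The authors deposited 1 site list that both libraries' labels name. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 1.13 and Bowtie 1.1.2 were used with the genome build hg19. The site names in the deposited list carry the name of the site caller rbsSeeker. Its settings, the treatment of reads that match several places, the threshold, and whether the libraries were pooled before or after calling are not given in the sources used here. The list has no column per library, so the spread between the 2 replicates could not be measured, and errors given here cover the counting of sites only. No library without the HA antibody, input RNA or expression table was analysed here.

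Each row of the deposited list held an interval of 201 nt, a name, a strand and a score. The deposited score is the authors' own value, a whole number of at least 3, and its unit is not given in the sources used here. Scores were used only to describe, rank and filter sites within this list. The numbers in the 5981 names ran from 1 to 5981 without repeats. The middle base of each interval, 100 nt from either edge, was taken as the position of the site, and coordinates are 1-based on hg19. Read depth per library is unknown.

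The gene annotation at hand was GENCODE 29, which is on GRCh38. Its build was compared with that of the sites by counting sites in protein-coding exons on the site's strand as deposited and after shifts in steps of 500 nt up to 300 kb. For this, sites of 1 strand within 1 kb were counted once. The deposited coordinates were among the top 1% of the 1201 positions tried on 4 of 24 nuclear chromosomes (5, 9, 18 and 19), and on the median chromosome 25.1% of the positions placed as many sites in exons. Over all nuclear sites, 5.33% lay in GRCh38 exons as deposited against 2.02 to 2.76% after shifts of 1 or 2 Mb, so the deposited coordinates did place some excess in exons (without chromosome 19, 4.15% against 1.98 to 2.65%). Since the processing notes name hg19 and most chromosomes showed no match, the sites were not joined to GRCh38 genes, and no coordinates were converted. The planned region shares, distances to stop codons, motif tests, gene lists and base check need hg19 sequence or annotation and were not run. The fallback rule for naming, set out with them, named the 10 windows of 1 kb with most sites (ties by summed score) and the 3 sites with the highest score. The numbers and exonic lengths of protein-coding genes per chromosome were taken from GENCODE 29, since they need no site coordinates. Annotated chromosome length was the coordinate at which the last protein-coding exon in GENCODE 29 ends, so stretches without genes before it are counted.

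Sites were counted per chromosome and strand, and strand shares were tested with two-sided exact binomial tests against 50% with Benjamini-Hochberg adjustment over 25 chromosomes. A site had a neighbour when another site lay within 30 nt on the same strand (alternatives 10 and 100 nt). Consecutive sites no more than 1 kb apart on either strand formed a locus, and loci of at least 5 sites are called dense loci. Whether neighbouring sites within 1 kb shared a strand was tested with 10000 permutations of strands over sites, two-sided. Scores were compared as differences of medians with 100000 permutations, two-sided, adjusted over 4 comparisons, and intervals of medians came from 1000 bootstrap resamples of loci. Permutations treat sites as independent, which sites of 1 transcript are not. Sites per autosome were related to protein-coding genes, exonic length and annotated chromosome length with Pearson's r and Spearman's rho, each with a permutation test of 100000 resamples, adjusted over these 6 relations. The 19 nuclear loci of at least 8 sites were compared in pairs, in both orientations, for sites at 1 common offset, against up to 10000 redraws of positions; the 2 loci of chromosome M were left out of this comparison. The tests of strand, score, loci and chromosomes took the place of the planned ones and were chosen after the site list had been seen; only the site counts, the spacing limits and the fallback rule for naming were fixed before the data were examined. Shares of sites have 95% Wilson intervals.

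The tests of shared strands, of score medians, of correlations, of chromosome groups and of copies were tested on simulated data first; the exact binomial tests and the build comparison were not. The simulated chromosome group was larger than the group of 2 tested below, so it does not show the power of that test. With strands drawn at random over the 5981 positions, 48.8% of neighbours within 1 kb shared a strand, and with 80% planted the estimate was 78.0%. None of the 50 score tests on shuffled scores gave p under 0.05. Scores have many ties and shuffling removes their clustering within loci, so this says little about false calls in the real list. Of 6 simulated loci, the single pair with 9 of 12 sites planted at 1 offset was the only one called. The simulated positions were drawn evenly over a span, as the redraws assume, so the effect of clustered sites was not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.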

Results

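The PAR-CLIP list of HA-METTL14 in HepG2 cells, made from 2 libraries, held 5981 T-to-C sites on 25 chromosomes, of which 31 were on the mitochondrial chromosome (M). Sites were split evenly between strands, with 3008 on the plus and 2973 on the minus strand (50.3% plus, 95% Wilson interval 49.0 to 51.6%, exact binomial p = 0.66). The authors' score, a whole number whose unit is not given in the sources used here, ran from 3 to 1855548 with a median of 5 and quartiles of 3 and 14. Many sites lay at the lowest value: 1543 sites, 25.8% (24.7 to 26.9%), had a score of 3. The list has 1 value per site over both libraries, so no value below has an error between replicates. No control library was analysed here, so there was no background to set against the sites. They show where the list places T-to-C changes, and crosslinking at each site was not tested.

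The first question was where in the genome the sites lay. Autosomes rich in protein-coding genes carried more sites. Chromosome 1, with 2043 protein-coding genes, held 542 sites, chromosome 2 held 507, chromosome 19 held 404, chromosome 17 held 364 and chromosome 16 held 356. The lowest numbers among autosomes were on chromosome 13 with 93 sites, chromosome 18 with 76 and chromosome 21 with 59. Chromosome 19, far shorter than chromosome 1, held 404 sites on 1472 genes, or 0.274 sites per gene, close to the 0.265 of chromosome 1. Over the autosomes, sites per gene ran from 0.198 on chromosome 15 to 0.416 on chromosome 16, and chromosomes 20 (0.409) and 2 (0.407) came next.

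Over the 22 autosomes the number of sites followed the number of protein-coding genes (Pearson's r = 0.93, Spearman's rho = 0.94, permutation p = 1e-05 for each, the smallest that 100000 resamples can give, adjusted p = 1.5e-05). It followed exonic length to a like extent (r = 0.91, rho = 0.91, permutation p = 1e-05 for each, adjusted p = 1.5e-05). The relation to annotated chromosome length was looser (r = 0.59, permutation p = 0.00346, adjusted p = 0.00415; rho = 0.48, p = 0.0253, adjusted p = 0.0253). With both measures taken as residuals on chromosome length, the relation to genes remained at r = 0.89 (permutation p = 1e-05). With both taken as residuals on the number of genes, the relation to length was r = 0.20 (permutation p = 0.379). Without chromosomes 1 and 19, the farthest from the median number of genes, r with genes was 0.91 (permutation p = 1e-05).

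**Figure D1:**
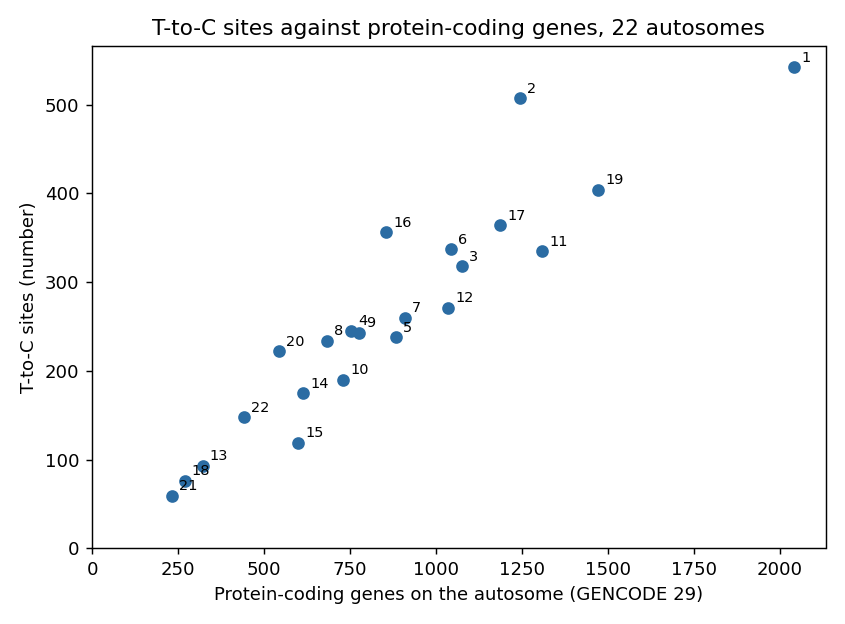
Number of T-to-C sites (y axis) against number of protein-coding genes (x axis, GENCODE 29), with 1 labelled point per autosome. Points rise together (r = 0.93), and chromosomes 2, 16 and 20 lie above the others with a like number of genes.

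The second question was whether the sites carried the strand of transcripts. Neighbouring sites lay on the same strand far more often than strands drawn at random, and this faded with distance. Of 447 neighbouring pairs within 30 nt, 445 shared a strand, 99.6% (98.4 to 99.9%). The share was 97.5% (94.6 to 98.8%) of 238 pairs from 31 to 100 nt, 90.3% (86.7 to 93.0%) of 341 pairs from 101 to 1000 nt and 85.0% (81.9 to 87.7%) of 581 pairs from 1001 to 10000 nt. It was 61.5% (58.7 to 64.2%) of 1205 pairs from 10001 to 100000 nt. Between 100001 and 1000000 nt it was 51.6% (49.5 to 53.6%) of 2264 pairs, an interval that includes 50%.

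Within 1 kb, 985 of 1026 pairs shared a strand, 96.0% (94.6 to 97.0%), against 50.0% over permuted strands (permutation p = 0.0001, the smallest that 10000 permutations can give). The interval and p-value treat pairs as independent, though 447 of them lay within 30 nt and can share reads, so both overstate the evidence. With same-strand sites within 30 nt merged to 1, the share was 92.9%. Outside dense loci, without this merging, the share was 96.5% (94.7 to 97.7%) of 596 pairs.

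**Figure D2:**
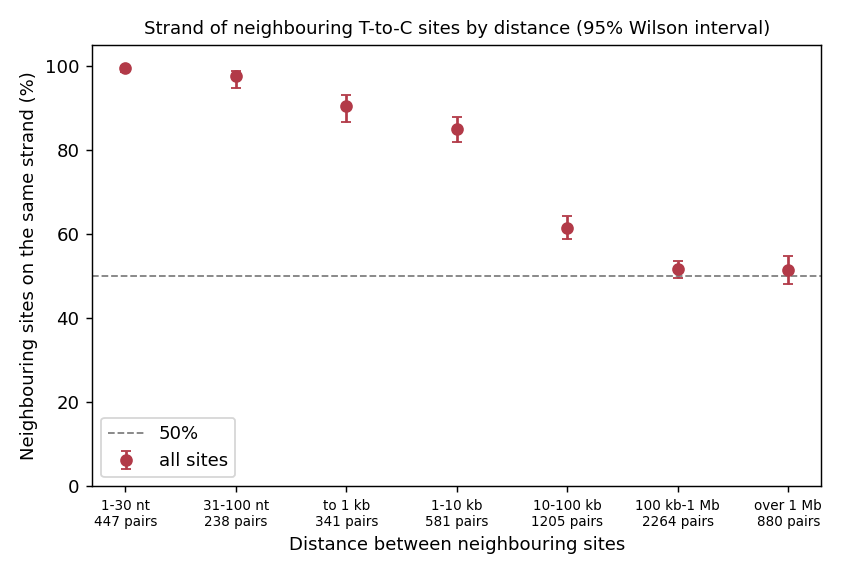
Percent of neighbouring sites on the same strand (y axis, points with 95% Wilson intervals) by distance between them (x axis, 7 bins with their numbers of pairs). The share falls from 99.6% within 30 nt to 51.6% between 100 kb and 1 Mb, where the dashed line at 50% lies within the interval.

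Most sites stood alone. Of the 5981 sites, 788 had another site on the same strand within 30 nt, 13.2% (12.3 to 14.1%), in 343 groups of up to 9 sites. Among spacings up to 100 nt, the shortest were the most frequent: 228 pairs of same-strand neighbours were 1 to 10 nt apart, 137 were 11 to 20 nt apart and 80 were 21 to 30 nt apart. The 5981 sites fell into 5095 windows of 1 kb, and 4597 of these windows, 90.2%, held 1 site.

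A small number of loci stood out from this background. In all, 39 dense loci on 19 chromosomes held 469 sites, 7.84% of the list (7.19 to 8.55%), and 65.7% of the summed score. A few loci carried much of that score: one on chromosome Y from 10037647 with 8 sites (27.6% of the summed score of the list), one on chromosome X from 108297347 with 7 sites (11.8%), one on chromosome 19 from 24182962 with 52 sites (8.87%) and one on chromosome 11 from 85195075 with 6 sites (4.46%), while 30 of the 39 held under 1% each. Without the chromosome Y locus, a setting chosen after the scores were seen, the dense loci held 52.7% of the remaining summed score. Of the 39, 31 had every site on 1 strand, 12 on the plus and 19 on the minus strand. The dense locus with most sites, on chromosome 2 from 133036280 to 133039176, held 58 sites, 57 of them on the minus strand. A locus on chromosome 19 from 24182962 to 24186099 held 52 sites, 50 on the minus strand. A locus on chromosome 16 from 33962614 to 33965725 held 48 sites, 47 on the plus strand. A further locus on chromosome 2, from 133012070 to 133013726, held 27 sites, all on the minus strand, and a locus on chromosome Y from 10034982 to 10036586 held 24, all on the plus strand.

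The 10 windows of 1 kb with most sites held 160 sites, 2.68% of the list (2.30 to 3.12%), and all lay in 6 of the dense loci. The window at 33963001 to 33964000 on chromosome 16 was first with 25 sites and a median score of 442. Chromosome 19 had the windows starting at 24184001 with 20 sites (median score 556.5) and at 24185001 with 14 (median score 187.5). Chromosome 2 had 5 of the 10: 18 sites from 133038001, 17 from 133037001, 15 from 133012001, 14 from 133036001 and 12 from 133013001. The window from 10036001 on chromosome Y held 12 sites with a median score of 1269. The window from 69218001 on chromosome 8 held 13 sites on both strands, 4 plus and 9 minus. Genes and sequence at these windows were not analysed here, since the annotation at hand is on another genome build.

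**Figure D3:**
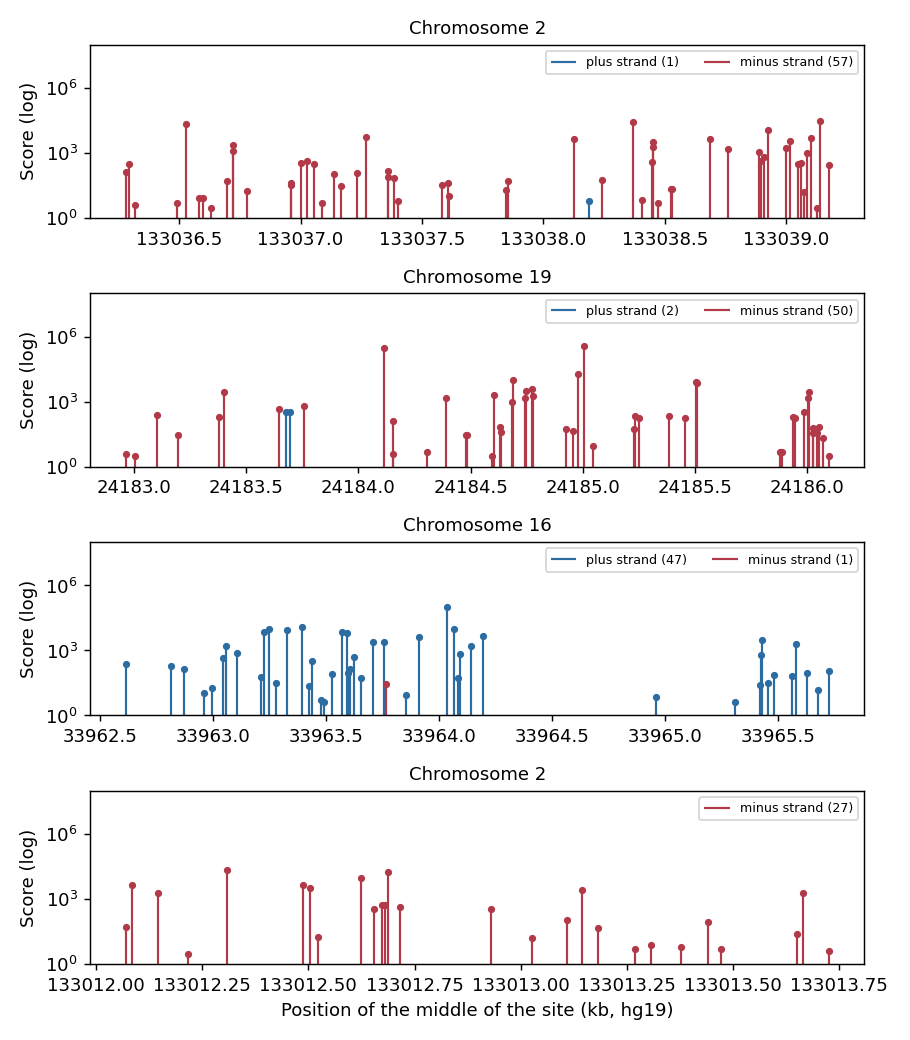
Each vertical line is a T-to-C site at its position (x axis, kb on hg19) with its score (y axis, log scale), blue on the plus and red on the minus strand, for the 4 dense loci with most sites. The loci on chromosomes 2 and 19 are nearly all minus (57 of 58, 50 of 52 and 27 of 27 sites) and that on chromosome 16 is plus (47 of 48).

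The strands of 6 chromosomes were unequal at an adjusted p under 0.05 in the exact binomial test (8 at an unadjusted p under 0.05). In these exact tests chromosome 2 had 39.6% of its sites on the plus strand (adjusted p = 8.95e-05), chromosome 8 39.7% (adjusted p = 0.0171), chromosome 16 57.6% (adjusted p = 0.0306), chromosome 4 58.4% (adjusted p = 0.0445), chromosome Y 79.3% (adjusted p = 0.000103) and chromosome M 74.2% (adjusted p = 0.0445). With sites of 1 strand within 1 kb counted once, none of the 25 chromosomes passed this exact test (3 had an unadjusted p under 0.05, chromosomes 3, 12 and 14, none of the 6). On chromosome 2 the plus share was then 50.0% of 370 sites, on chromosome 16 it was 51.7% of 269 and on chromosome Y 54.2% of 24. Chromosome 8 stayed below 50%, at 43.0% of 186 (exact binomial p = 0.0665, adjusted p = 0.413). Chromosome 4 stayed above it, at 55.3% of 208 (exact binomial p = 0.145, adjusted p = 0.605). On chromosome M, where most textbook genes read from the plus strand, the plus share was 69.2% of 13.

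The third question was how the score was spread over the list. It was very unequal. The site with the highest score, 1855548, lay at 10037768 on the plus strand of chromosome Y and held 22.5% of the summed score. Next were 837918 at 70602341 on the minus strand of chromosome 8 and 752110 at 108297375 on the plus strand of chromosome X. These 3 sites held 41.9% of the summed score and the first 10 held 66.2%. Only 587 sites, 9.81%, had a score of at least 100, and 63 had at least 10000.

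Sites in dense loci had a median score of 94 (95% bootstrap interval 56.5 to 144, 469 sites) against 5 (5 to 5, 5512 sites) elsewhere (permutation p = 1e-05, adjusted p = 2e-05). Only sites with a score of at least 3 are listed, and dense loci are defined by the number of listed sites. Density and score can therefore be linked through the list itself, also for sites with a near neighbour. The 469 sites came from 39 loci and are not independent, so the p-value overstates the evidence. Sites with a same-strand neighbour within 30 nt had a median of 23 (13 to 36, 788 sites) against 5 (5 to 5, 5193 sites) for the rest (permutation p = 1e-05, adjusted p = 2e-05). Outside dense loci this difference of medians was 3 in place of 18 (permutation p = 0.0001). The 31 sites on chromosome M had a median of 39 (7 to 81) against 5 (5 to 6) on the other chromosomes (permutation p = 2e-05, adjusted p = 2.67e-05). These 31 sites fell to 13 when sites of 1 strand within 1 kb were counted once, so this p-value overstates the evidence. The median was 5 on both strands (permutation p = 1, which a difference of 0 always gives). By mean log2 score, the plus strand differed from the minus strand by -0.123 (permutation p = 0.0613).

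**Figure D4:**
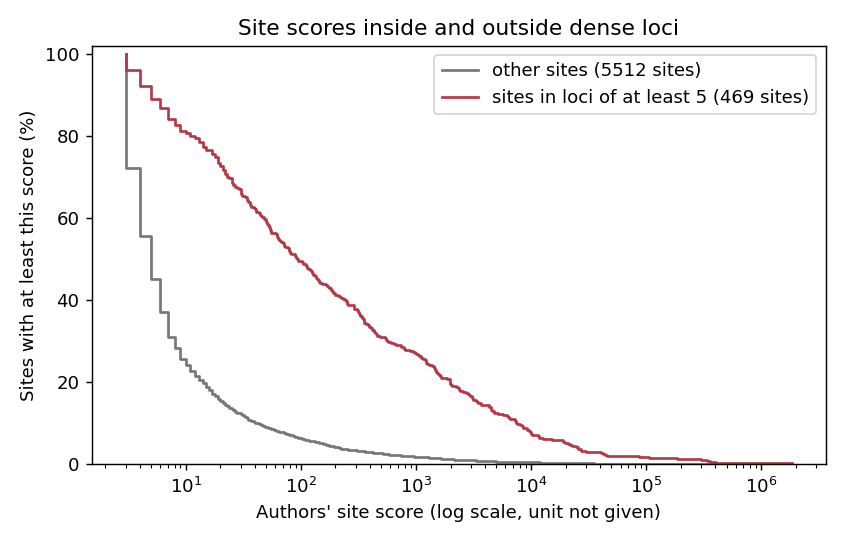
Percent of sites (y axis) with at least a given score (x axis, log scale, unit not given), for the 469 sites in dense loci and the 5512 other sites. The curve of dense loci lies to the right throughout, with medians of 94 and 5.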

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

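The spacing limits of 10 and 100 nt for the share of sites with a neighbour were planned; the other alternatives were chosen after the site list was seen. Of 30 values recomputed, 22 kept their direction and their side of the threshold, or stayed within the interval of the reported value. The share of sites with a same-strand neighbour, 13.2% at 30 nt, was 7.34% at 10 nt and 18.0% at 100 nt, as a narrower or wider limit must give. It was 16.6% among the 3502 sites with a score of at least 5, 27.2% among the 1496 with at least 14 and 9.11% without dense loci. The share of sites in the 10 fullest windows was 4.37% among sites with a score of at least 5, against 2.68%. The dense loci held 52.7% of the summed score without the locus with the highest summed score, against 65.7%. The number of chromosomes with unequal strands went from 6 to 0 when sites of 1 strand within 1 kb were counted once, a setting that leaves 4987 sites. The same-strand share within 1 kb stayed between 92.9% and 97.9% over its 5 alternatives. The r of sites with genes stayed between 0.87 and 0.95 over its 7, 1 of which took exonic length in place of the number of genes. No paired analysis was possible because the series has 1 group, and leaving out a replicate was not possible because the list gives 1 value over both libraries. The planned tests of regions, stop codons, motifs, 4-mers, gene lists, score by region and the base at the site were not run without hg19 sequence and annotation. The depth of the libraries is unknown, so a place without a site is not shown to be unbound.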

Other observations

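The mitochondrial chromosome held sites along most of its length, from 146 to 16225, with the highest scores close together at 2896 (40639) and 2897 (25634) on the plus strand. Of the 39 dense loci, 8 held sites on both strands. In 3 of these, on chromosomes 2, 19 and 16, at least 96.2% of the sites lay on 1 strand. The other 5, where that share was under 90%, were both loci of chromosome M, with 9 plus and 2 minus sites from 2896 and 6 plus and 5 minus from 12706, a locus on chromosome 1 from 565527 to 568828 with 5 plus and 3 minus, a locus on chromosome 5 from 134261646 to 134263686 with 2 plus and 3 minus, and a locus on chromosome 8 from 69218475 to 69218896 with 4 plus and 9 minus. A locus on chromosome 5 from 79946375 to 79947342 had 8 sites, all minus, with a highest score of 41853.

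The tests in this part were chosen after the results they bear on were seen, except that of dense loci as the source of the shared strands. The first pattern is the dense loci. Genomic DNA as the source of these loci as a set is argued against only in part. Of 430 neighbouring pairs in these loci, 95.3% (92.9 to 97.0%) shared a strand, where separate DNA fragments would give about 50%. Pairs a few nt apart can lie on the same reads, though, and would then share a strand from DNA too. The dense loci with most sites, on chromosomes 2, 19 and 16, spanned at least 2897 nt. Of their sites, 98.3%, 96.2% and 97.9% lay on 1 strand, which argues against DNA for these loci. The loci on chromosomes 16 and Y may be copies of 1 sequence: 8 of the 24 sites from 10034982 on chromosome Y matched chromosome 16 sites at 1 offset (permutation p = 0.0001, the smallest that 10000 redraws can give, adjusted p = 0.0342 over 342 pairs and orientations), and 6 of the 8 sites from 10037647 matched at an offset that differed by 11 nt (adjusted p = 0.0684), among them the site with the highest score. The redraws spread positions evenly over each locus, while listed sites cluster, so these p-values may be too small. That all reads were recorded at both places is argued against, as 0 of the 14 matched sites had equal scores. The higher score was 1.29 to 588 times the lower. Unequal scores cannot exclude that part of the reads was recorded at both places, or that reads were divided between them. The treatment of reads that match several places is not given. Whether the loci are only abundant RNA, such as a multi-copy structural RNA, stays open, because the series has 0 control libraries among its samples.

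The second pattern is that sites shared the strand of their neighbours. A few dense loci as the source are argued against, as the lower bound of the interval within 1 kb without them was 94.7%. Every one of the 353 pairs within 100 nt then shared a strand, but pairs this close can lie on the same reads. From 101 to 1000 nt the share without dense loci was 91.4% (87.2 to 94.3%) of 243 pairs. Transcription of both sites as 1 RNA is a candidate explanation that the fade to 51.6% beyond 100 kb would fit; transcript bounds on hg19 were not analysed here, so no biological explanation was tested.

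The third pattern is the excess of sites per gene on chromosomes 16 (0.416), 20 (0.409) and 2 (0.407), against 0.286 ± 0.035 (SD) over the other 19 autosomes. These 3 were picked for their rank. Each was also set against all 21 other autosomes, the other 2 among them, which does not correct for that choice. Dense loci as the whole cause are argued against for chromosome 20, which had 214 of its 222 sites outside these loci. Without the loci it had 0.394 sites per gene, 3.06 SD above the other 21 (0.280 ± 0.037). For chromosomes 16 and 2 they stay open: without them chromosome 16 had 0.347, 1.53 SD above its other 21, and chromosome 2 had 0.324, 0.922 SD above, while chromosome 22 had 0.335. The value of chromosome 16 depends on the reference, as it lay 2.16 SD above the 19 autosomes that leave out all 3 (0.274 ± 0.034). HepG2 is described as carrying extra copies of chromosomes 2, 14, 16, 17 and 20, a list taken from general knowledge of the line after the counts were seen, so only chromosomes 14 and 17 could test it. These had 0.285 and 0.303 sites per gene without dense loci against 0.271 ± 0.035 over 17 autosomes (two-sided exact permutation p = 0.439), and with 2 chromosomes this neither bears out nor excludes extra copies as a source of the excess.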
